A study of Mus musculus with 6 samples.

How the data were processed

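Total RNA was measured by sequencing of directional libraries from macrophages differentiated from bone marrow of adult male mice in medium with 20% L929-conditioned medium and 10% FBS, per the labels' protocols. Groups were taken from the genotype in the sample labels, 3 WT and 3 KO, and replicates were numbered in the order of the samples because the labels give no replicate number. Per the submitters' processing notes, DRAGEN, DESeq2 and the build mm10 were used, without versions or roles. The annotation, the strand setting and the way of counting are not given in the sources used here, so genes that overlap or lie antisense to another gene, and near-identical copies such as Hspa1a and Hspa1b, may share counts.

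The deposited counts are whole numbers per Ensembl gene for 42256 genes, of which 21695 had a count in any library and 42170 matched a symbol in the GENCODE M21 annotation of GRCm38, the assembly also called mm10; all coordinates come from that annotation. The authors also deposited a normalized signal per gene. Per the file headers its columns are the same 6 samples, and its values equal the counts divided by factors that differ between genes as well as libraries, with a geometric mean of 1 over the 6 libraries of each gene. In 57.0 to 72.4% of the 12835 genes compared, depending on the library, the factor lay more than 1% from that library's median. This form is that of gene-specific normalization factors, so the counts may be rounded estimates, which no source states. Totals were 37113689, 27170943 and 28985052 counts for WT 1 to WT 3 and 28193880, 28967368 and 30122204 for KO 1 to KO 3. Mitochondrial genes took 2.09 to 2.43% of counts, and the 10 most abundant genes 11.9 to 13.8%.

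Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotype (minimum count 10), leaving 12862, scaled by TMM, and tested with the robust quasi-likelihood F test of KO against WT without covariates. P-values are two-sided, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM use TMM-scaled totals, and logarithms for principal components a prior count of 2; the per-library CPM of Cdh11, Xist and Y-linked genes use plain totals. Cdh11 failed the filter and was added to the genes kept for its own test. The biological coefficient of variation was 0.121. Counts of replicate libraries differed by more than sampling noise in each pair, with a chi-square per degree of freedom of 12.57 to 52.5. Thus none was treated as a second copy of another, which does not show that they came from separate animals.

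Before the data were examined, 31 gene lists (20 of pathways, 11 of markers of other cells) were fixed and tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Named genes followed a rule also fixed then: Cdh11; up to 12 rises and 12 falls of the largest fold change among called genes with a mean log2 CPM of at least 1, non-overlapping genotypes and a symbol that is not a predicted model; up to 4 called members per list with the largest change; and up to 8 called genes within 10 Mb of Cdh11 by smallest p. Some genes that the rule selects are not reported here. Where a further gene is named, it was chosen after its values were seen. Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings and filters, limma on log2 of the deposited signal plus 1, and leaving out each library.

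The test was tried on simulated counts with the means and library sizes of the 12862 genes of this comparison, 200 of them changed. edgeR recovered 56.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 97.0% of those changed 4-fold. In this first draw 22 of its 175 calls were false, 49 of 211 for DESeq2 and 18 of 166 for limma-voom, all above the nominal 5%. A further 10 edgeR draws per setting were added after that result. They gave a mean of 8.30% false calls with 200 changed genes (5.66 to 10.7%). With 4500 changed genes, a number close to the calls in the real comparison, the mean was 2.97% (2.61 to 3.43%). Genes were drawn as independent, with changes of 1.5-, 2- or 4-fold. The real called genes had a median absolute log2 fold change of 0.45, so these shares are not false-call rates of the real comparison. Camera with the preset correlation gave p under 0.05 for 3 of 200 simulated lists without change, whose genes were drawn as independent, so correlated genes were not covered.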

Results

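RNA was sequenced from bone marrow-derived macrophages of adult male mice with an intact Cdh11 gene (wild type, WT) or without it (knockout, KO). Bone marrow-derived macrophages are obtained by growing marrow progenitors in medium that carries the macrophage growth factor CSF1. Here the source was 20% L929-conditioned medium for 7 days. Cdh11 encodes cadherin-11, an adhesion protein best known from fibroblasts and osteoblasts. The series sets the comparison in atherosclerosis, with macrophage migration and T cell activation as its themes. The cultures were untreated, and 3 WT and 3 KO libraries entered the comparison, with 27170943 to 37113689 counts each. That the libraries come from separate animals is stated only in the design text of the series, which mentions 4 KO animals. The sample labels do not name animals, so p-values measure the spread between these libraries. Values are CPM, counts scaled to the library total after TMM scaling (plain totals for Cdh11, Xist and Y-linked genes), as mean ± SD with n = 3 per genotype, and a gene is said to have risen or fallen in KO only where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05.

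Cdh11 itself (ENSMUSG00000031673, GRCm38 chromosome 8, 102632095 to 102785642, minus strand) was close to the limit of detection in both genotypes. WT libraries held 6 to 11 counts and KO libraries 4 to 6, or 0.258 ± 0.129 against 0.172 ± 0.0378 CPM, where 3 counts correspond to 0.0808 to 0.110 CPM. The log2 fold change was -0.55 (SE 0.51; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.423), and a two-sided exact permutation test gave p = 0.5, with 0.1 the smallest value that 3 against 3 libraries allow. The transcript therefore does not check the genotype labels, since no difference was detectable at this depth and counts over the whole gene do not separate intact from deleted parts. All 6 libraries carried Y-linked transcripts (Ddx3y at 28.2 to 71.8 CPM) and 2 to 7 Xist counts, as for the male mice of the labels.

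KO macrophages differed from WT macrophages across a large part of the transcriptome. Of 12862 genes tested, 4532 (35.2%) passed the threshold, 2375 of them higher and 2157 lower in KO. Most changes were small, with a median absolute log2 fold change of 0.45 among called genes. By at least 2-fold, 471 genes rose and 186 fell. The CPM of the genotypes did not overlap for 6866 genes (53.4%, where chance gives 10%). On the first principal component, 66.97% of the variance of the 500 most variable genes, WT libraries lay at -18.79, -22.86 and -12.21 and KO libraries at 7.11, 28.36 and 18.39, KO 1 being the KO library nearest to WT. The number of called genes depended on single libraries: it was 1979 without WT 1, 2484 without WT 2, 2721 without KO 2 and 2384 without KO 3. It was 3679 without WT 3 and 5456 without KO 1. Fewer libraries also lower the power of the test, so a lost call does not by itself show a smaller difference. Without WT 2 and KO 2 together, an alternative added after the data were seen, it was 1370.

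**Figure D1:**
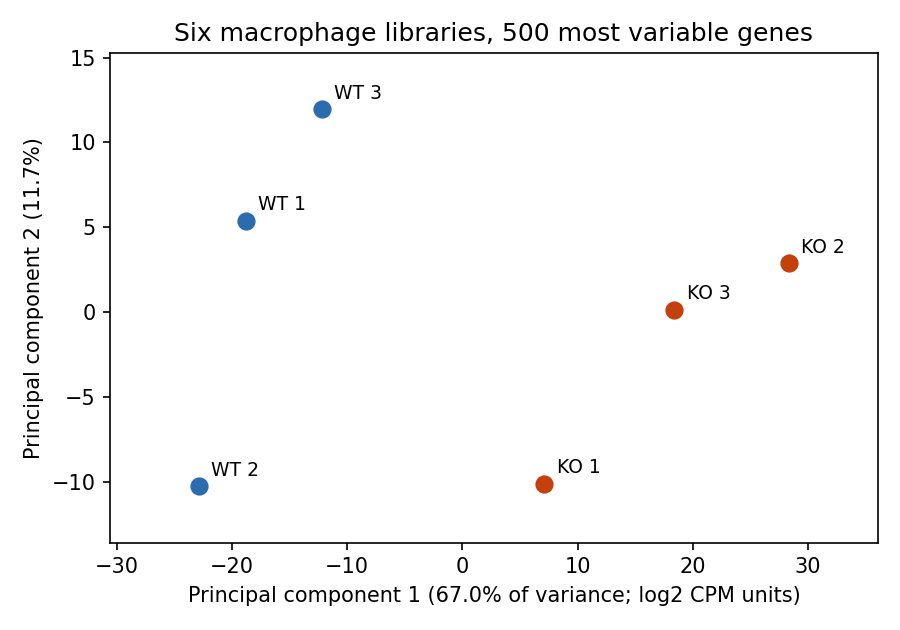
Scores of the 6 libraries on the first and second principal components of log2 CPM over the 500 most variable genes, with each point a library coloured by genotype. The first component, 67.0% of the variance, places all WT libraries below -12.2 and all KO libraries above 7.1.

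Among called genes with a mean log2 CPM of at least 1, those with the largest falls in KO included enzymes of leukotriene synthesis and surface receptors. Alox5, the 5-lipoxygenase that starts leukotriene synthesis (ENSMUSG00000025701, chromosome 6, 116410077 to 116461178, minus strand), fell 6.17-fold, from 15.3 ± 7.81 to 2.47 ± 0.386 CPM. Ltc4s, which makes leukotriene C4, fell from 24.2 ± 2.76 to 5.55 ± 1.71 CPM. Cd33, a sialic acid-binding receptor (ENSMUSG00000004609, chromosome 7, 43524216 to 43544428, minus strand), fell from 207 ± 12.4 to 50.1 ± 23.4 CPM (log2 fold change -2.05, SE 0.36). The ADP receptor genes P2ry12 and P2ry13, neighbours on chromosome 3 that overlap the oppositely oriented gene Med12l, fell from 28.9 ± 7.48 to 7.25 ± 2.699 CPM and from 53.7 ± 15.1 to 13.9 ± 6.22 CPM. Cbr2, a carbonyl reductase, fell from 19.4 ± 2.09 to 4.22 ± 1.75 CPM, and the ribosomal protein paralog Rpl3l fell from 4.22 ± 0.387 to 1.05 ± 0.493 CPM. Ripor2, a RhoA inhibitor, fell by 2.01 on the log2 scale, although its call was lost without WT 1 or KO 3. Adjusted p for these 8 genes ran from 0.00495 to 0.0143 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

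Among called genes with a mean log2 CPM of at least 1, the largest rise was that of Mgll, monoacylglycerol lipase, which went from 1.62 ± 0.268 to 13.99 ± 12.2 CPM. Its KO libraries were spread, at 8.14, 28.01 and 5.81 CPM, and its call was lost without WT 1. Ptprn, a secretory granule protein, rose 7.61-fold, from 1.31 ± 0.429 to 10.05 ± 3.94 CPM. Mmp9, the gelatinase that degrades type IV collagen (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850, plus strand), rose 7.37-fold, from 8.298 ± 2.25 to 60.6 ± 24.6 CPM. Itga2b, the platelet integrin alpha chain, rose from 0.8102 ± 0.259 to 5.21 ± 1.41 CPM, and F7, coagulation factor VII, rose from 2.06 ± 0.331 to 12.1 ± 7.501 CPM. Lat, an adaptor of T cell receptor signalling, rose from 1.62 ± 0.489 to 8.92 ± 3.95 CPM, and Fam78b rose from 3.46 ± 1.46 to 17.3 ± 5.11 CPM. Fgfr1, a fibroblast growth factor receptor, Ctsk, the collagenase cathepsin K of osteoclasts, Cd200, an immune inhibitory ligand, Mamdc2 and Dio2, a thyroid hormone deiodinase, rose by log2 fold changes of 2.82, 2.49, 2.48, 2.51 and 2.40. Each of these last 5 lost its call without WT 1; Ctsk also did so without WT 2, Cd200 without WT 3, Mamdc2 without WT 2 or WT 3, and Dio2 without WT 2, WT 3 or KO 3. KO 2 was the highest library for Mgll, F7 and each of these 5, with F7 at 6.92, 20.7 and 8.67 CPM and Ctsk at 5.93, 26.6 and 10.9 CPM in KO 1 to KO 3. Without KO 2 their calls held, but the log2 fold changes were 2.11 for Mgll, 1.91 for F7, 2.22 for Fgfr1, 1.72 for Ctsk, 1.72 for Cd200, 1.71 for Mamdc2 and 1.66 for Dio2.

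Most genes of cholesterol synthesis and sterol sensing fell. Of 24 measured members, 18 fell and 0 rose, and 19 fell when adjusted over the list alone; the median log2 fold change was -0.51. Insig1, which retains the sterol sensor in the endoplasmic reticulum (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662, plus strand), fell from 129.9 ± 6.11 to 60.3 ± 6.39 CPM (log2 fold change -1.11, SE 0.08). Stard4, a sterol carrier, fell from 60.5 ± 4.69 to 29.1 ± 2.57 CPM. Limma's camera called the list (Benjamini-Hochberg adjusted p = 2.75e-08 with the preset correlation; adjusted p = 0.916 and unadjusted p = 0.0823 with an estimated correlation). It was also the one list that passed fry, which tests whether a set's genes move on balance one way (adjusted p = 0.0289). In the list of lipid uptake and efflux, 9 of 29 members rose and 5 fell (10 and 5 adjusted over the list alone). Cd36, a receptor for oxidised lipoprotein and fatty acids, rose from 577 ± 149.8 to 1910.0 ± 535 CPM. Nr1h3, the sterol-activated nuclear receptor LXR alpha (ENSMUSG00000002108, chromosome 2, 91184061 to 91202834, minus strand), rose from 20.3 ± 1.77 to 45.9 ± 1.55 CPM (log2 fold change 1.18, SE 0.08), and Fabp4, a fatty acid-binding protein, rose from 19.1 ± 2.01 to 50.2 ± 10.6 CPM. Camera did not call the lipid list (adjusted p = 0.457), and the 5 falls became 3 without WT 1, WT 2, KO 2 or KO 3.

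Among genes of macrophage identity and uptake, several abundant receptors fell. Mrc1, the mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057, plus strand), fell from 1948 ± 121 to 903 ± 72.6 CPM (log2 fold change -1.11, SE 0.09). Stab1, a scavenger receptor, fell from 3948 ± 384 to 1923 ± 249 CPM, Gas6, a bridging ligand for apoptotic cells, from 1091 ± 56.03 to 544 ± 109 CPM, and Fcgr2b, the inhibitory Fc gamma receptor, from 564 ± 135 to 226 ± 66.6 CPM, a call lost without a filter. Csf1r, the receptor for the growth factor that maintains macrophages, fell from 3723 ± 315 to 2287 ± 372 CPM, whereas Lgals3, galectin-3, rose from 1038 ± 129 to 2174 ± 529.7 CPM. In the phagocytosis and efferocytosis list 2 of 30 members rose and 7 fell, with the same numbers adjusted over the list alone, the rises becoming 4 without KO 1 and 0 without WT 1, WT 2, KO 2 or KO 3 (2, 4, 5 and 5 at an unadjusted p under 0.05 in edgeR, the only test of single genes run there). DESeq2 called 4 rises and limma-voom 3. Of 18 core macrophage genes 3 rose and 4 fell (4 and 4 adjusted over the list alone), the median being 0.03 and the mean -0.01, and camera's direction down. Without 1 library the rises ran from 1 (without WT 1, WT 2, KO 2 or KO 3) to 6 (KO 1) and the falls went down to 1 (WT 1) or 2 (WT 2, WT 3 or KO 3). Alternative activation genes also went both ways, 5 of 15 rising and 4 falling (6 and 5 adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist, rose from 29.8 ± 7.36 to 109 ± 40.7 CPM, and Cd163, the haemoglobin scavenger receptor, fell from 3.58 ± 0.581 to 1.61 ± 0.372 CPM. None of these 3 lists was called by camera (adjusted p of 0.173, 0.977 and 0.953).

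**Figure D2:**
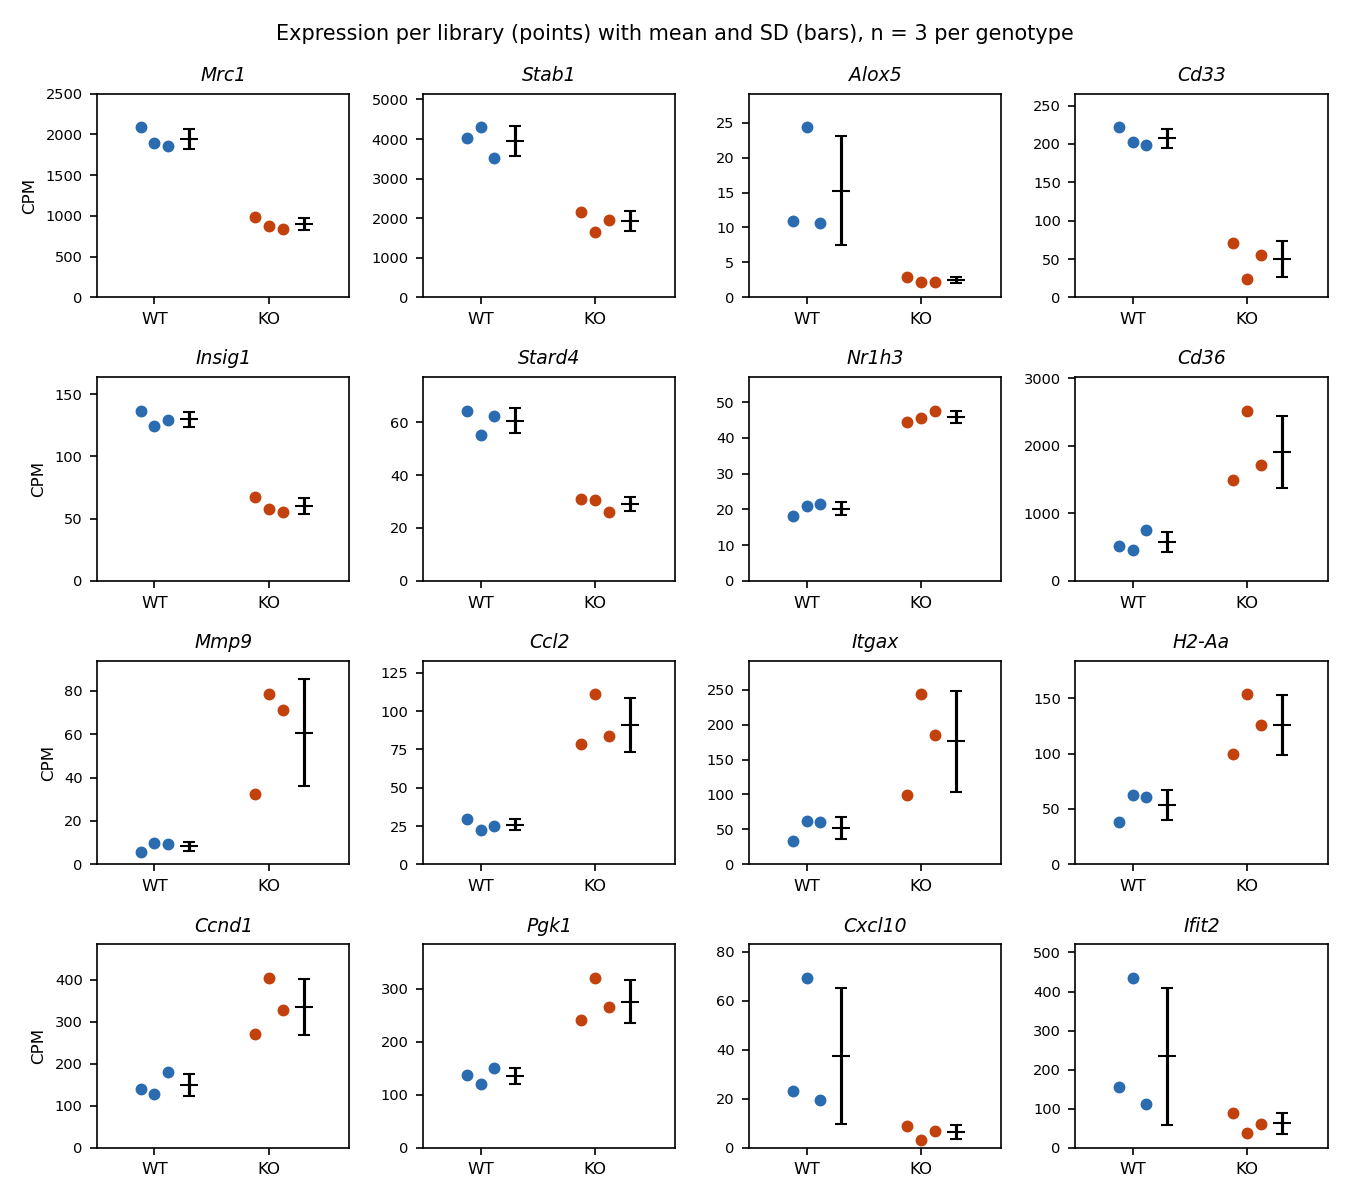
CPM of 16 of the named genes in each library (points, WT in blue and KO in orange), with the mean and SD of the 3 libraries per genotype beside them. Mrc1, Insig1 and Nr1h3 are tight within each genotype, whereas Cxcl10 and Ifit2 reach their highest values in WT 2, at 69.3 and 435 CPM.

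Genes for chemokines, matrix degradation and movement contained more rises than falls. For comparison, 35.2% of all 12862 tested genes were called, 2375 rising and 2157 falling. The share called in the cytoskeleton and migration list was not above that. Of 29 matrix remodelling genes 13 rose and 4 fell, with the same numbers adjusted over the list alone, the rises becoming 7 without WT 1 and the falls 2 without any 1 library except KO 1. Timp3, a metalloproteinase inhibitor, rose from 0.221 ± 0.0708 to 2.22 ± 0.611 CPM, and Fn1, fibronectin, listed among monocyte markers, rose from 13.98 ± 1.72 to 32.4 ± 8.03 CPM. Of 28 chemokines and their receptors 9 rose and 4 fell (10 and 7 adjusted over the list alone), with a median of -0.05 and a mean of 0.11. The rises became 5 without WT 1 and the falls 1 without WT 1, WT 2, KO 2 or KO 3, while DESeq2 called 7 falls and limma-voom 6. Ccl2 and Ccl7, which attract monocytes, rose from 25.8 ± 3.68 to 90.97 ± 17.4 CPM and from 6.76 ± 1.55 to 26.6 ± 5.79 CPM, and Ccl22, which attracts regulatory T cells, rose from 0.599 ± 0.136 to 3.12 ± 0.575 CPM. Of 38 cytoskeleton and migration genes 9 rose and 3 fell, as also adjusted over the list alone. The rises became 5 without WT 1 and the falls 5 without KO 1 and 1 without KO 3, and DESeq2 called 5 falls. Rhoc, a small GTPase, rose from 36.5 ± 2.999 to 85.4 ± 18.7 CPM, Plaur, the urokinase receptor, from 43.6 ± 3.34 to 83.7 ± 15.9 CPM, and Tpm1, tropomyosin, from 70.4 ± 8.44 to 127 ± 20.9 CPM. Camera called none of the matrix, chemokine and cytoskeleton lists (adjusted p of 0.119, 0.525 and 0.470).

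Adhesion genes moved in both directions. Of 26 integrin and adhesion genes 6 rose and 7 fell (7 and 8 adjusted over the list alone), with a median of 0.07 and a mean of 0.04 while camera's direction was down (adjusted p = 0.938). The rises became 1 without WT 1, 3 without WT 2 and 2 without KO 2 or KO 3, and the falls 4 without WT 1 or WT 2 and 3 without KO 2 or KO 3. Itga4, the integrin alpha 4 chain, fell from 280.2 ± 7.81 to 164 ± 30.4 CPM. Itgax, the integrin chain CD11c, rose from 51.9 ± 15.5 to 176 ± 72.6 CPM, a call lost without WT 1, KO 2 or KO 3. Of 12 measured cadherin and catenin genes 6 rose and 1 fell, as also adjusted over the list alone, and camera did not call the list (adjusted p = 0.119). The rises became 2 without WT 1 and 3 without WT 2, KO 2 or KO 3, and the 1 fall was lost without any 1 library except KO 1. Fat3, an atypical cadherin, rose from 0.332 ± 0.127 to 1.96 ± 0.917 CPM, and Ctnnd2, delta-catenin, rose from 0.584 ± 0.226 to 1.896 ± 0.487 CPM. Pcdh7, a protocadherin, rose from 146 ± 47.9 to 325 ± 82.00 CPM, a call lost without WT 1, WT 2, KO 2 or KO 3. Among 20 Wnt and TGF-beta targets 5 rose and 5 fell, as also adjusted over the list alone, with a median of -0.03, a mean of 0.05 and a camera direction of down (adjusted p = 0.953). The rises became 2 without WT 1 or KO 3 and 3 without WT 2 or KO 2, and the falls 2 without WT 1, WT 2 or KO 3 and 3 without KO 2. Ccnd1, cyclin D1, rose from 149.9 ± 26.6 to 335 ± 66.7 CPM and Tgfbi, a secreted matrix protein, fell from 184 ± 9.07 to 92.1 ± 14.97 CPM.

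Several genes for antigen presentation on MHC class II rose while several T cell costimulatory genes fell. H2-Aa, H2-Eb1 and H2-Ab1, chains of the class II molecules, rose from 53.8 ± 13.5 to 126 ± 27.04 CPM, from 35.2 ± 7.41 to 85.5 ± 22.8 CPM and from 40.4 ± 11.9 to 87.6 ± 21.8 CPM, and Cd74, the invariant chain, rose from 186 ± 52.4 to 377 ± 66.9 CPM. In the class II list 5 of 11 members rose and 1 fell (5 and 2 adjusted over the list alone), and camera did not call it (adjusted p = 0.235). The 5 rises became 2 without KO 2 or KO 3, the calls of H2-Ab1 and Cd74 being among those lost, and the 1 fall was lost without WT 2, WT 3, KO 2 or KO 3, while DESeq2 and limma-voom called 2 falls each. In the class I list 2 of 21 members rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.662). The class I falls became 1 without WT 1, WT 2, WT 3 or KO 1 and 0 without KO 2 or KO 3 (2 in each at an unadjusted p under 0.05 in edgeR), and the rises 1 without WT 1, WT 3 or KO 2. DESeq2 called 3 falls. Calr, a chaperone of the loading complex, rose from 855 ± 7.66 to 1278 ± 144 CPM, and Nlrc5, a transactivator of class I genes, fell from 54.2 ± 17.4 to 28.9 ± 3.84 CPM, a call lost without KO 1, KO 2 or KO 3. Of 22 costimulation genes 8 fell and 1 rose, as also adjusted over the list alone, with a median of -0.40. Tnfsf9, the ligand of 4-1BB, fell from 8.14 ± 1.24 to 4.66 ± 0.718 CPM, and Icosl, the ligand of ICOS, fell from 35.3 ± 7.93 to 13.3 ± 4.96 CPM, a call lost without KO 3. Tnfsf4, the ligand of OX40, rose at a low level, from 0.1105 ± 0.0289 to 0.422 ± 0.06801 CPM, a call lost without WT 1. Camera called the costimulation list with the preset correlation (adjusted p = 0.0234) but gave adjusted p = 0.916 with an estimated correlation, and the 8 falls became 5 without WT 1, 4 without WT 2, 5 without KO 2 and 2 without KO 3.

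Some interferon-stimulated genes fell in KO, with wide spread among WT libraries. Of 35 measured genes 10 fell and 0 rose, with a median log2 fold change of -0.96 (-0.43 without WT 2), and none passed edgeR's quasi-likelihood test adjusted over the list alone, where 22 had an unadjusted p under 0.05. DESeq2 called 21 of the 35 and limma-voom 14. Cxcl10, a chemokine induced by interferon, fell from 37.3 ± 27.8 to 6.36 ± 2.78 CPM, the WT libraries being at 23.2, 69.3 and 19.5 CPM. Ifit2, an antiviral RNA-binding protein, stood at 156, 435 and 113 CPM in WT, and fell from 235 ± 175 to 62.6 ± 25.8 CPM. Rsad2, the antiviral enzyme viperin, fell from 89.1 ± 56.7 to 29.3 ± 9.38 CPM, with 64.3, 154 and 49.1 CPM in WT. Without WT 2 the log2 fold changes of Cxcl10, Ifit2 and Rsad2 went from -2.55, -1.90 and -1.60 to -1.75, -1.11 and -0.96. Cxcl10 lost its call without any 1 of the KO libraries, Ifit2 and Rsad2 without WT 1, WT 2 or any 1 of the KO libraries. Camera called the list with the preset correlation (adjusted p = 3.54e-05), with adjusted p = 0.916 under an estimated correlation, and the 10 falls became 3 without WT 1, 6 without WT 2, 20 without WT 3, 4 without KO 1 and 0 without KO 2 or KO 3, where 5 and 12 genes had a lower value in KO at an unadjusted p under 0.05. Of 18 proinflammatory genes 2 rose and 6 fell, as also adjusted over the list alone, and camera did not call the list (adjusted p = 0.135). The falls were Socs3, Nlrp3, Irf1, Tlr2, Tlr4 and Nfkbia, and the rises Irf5 and Ccl4, so no cytokine or chemokine of this list fell. Tnf and Il1b did not pass (edgeR's quasi-likelihood test, adjusted p of 0.463 and 0.450). Ccl4, a chemokine, rose from 27.1 ± 2.41 to 34.8 ± 3.37 CPM. The 6 falls became 3 without WT 1 or WT 2 and 2 without KO 2 or KO 3, and the 2 rises 1 without WT 3 and 0 without WT 1 or KO 3 (2 in each at an unadjusted p under 0.05 in edgeR). Socs3, an inhibitor of cytokine signalling, fell from 14.7 ± 4.34 to 4.56 ± 0.973 CPM, Nlrp3, an inflammasome sensor, from 100.1 ± 11.6 to 59.99 ± 9.53 CPM, and Irf1, an interferon regulatory factor, from 134 ± 31.4 to 80.5 ± 10.6 CPM, the last losing its call without KO 2 or KO 3.

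Some cell cycle genes and some hypoxia and glycolysis genes rose in KO. Of 38 proliferation genes 19 rose and 0 fell, 26 rose when adjusted over the list alone, and the median log2 fold change was 1.00. DESeq2 called 25 rises and limma-voom 30. Ccne1, cyclin E1, rose from 3.398 ± 0.553 to 8.92 ± 2.25 CPM, and Tyms, thymidylate synthase, rose from 6.06 ± 2.08 to 15.3 ± 3.99 CPM, a call lost without WT 1. Camera called the list (adjusted p = 7.51e-09 with the preset correlation, adjusted p = 0.916 with an estimated correlation), and the 19 rises became 2 without WT 1, 7 without WT 2, 37 without WT 3, 6 without KO 2 and 6 without KO 3. Of 28 hypoxia and glycolysis genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), the falls becoming 1 without WT 1, KO 2 or KO 3. Pgk1, phosphoglycerate kinase, rose from 136 ± 14.99 to 275 ± 40.4 CPM, and Mif, a cytokine also induced by hypoxia, rose from 50.9 ± 1.13 to 118 ± 21.9 CPM. This list was called with the preset correlation (adjusted p = 0.000689) and had adjusted p = 0.916 with an estimated correlation. Of 25 NRF2 and oxidative stress genes 9 rose and 2 fell, as also adjusted over the list alone, and DESeq2 called 4 falls. Hmox1, haem oxygenase 1, rose from 525 ± 13.7 to 965 ± 176 CPM and Gpx1, a glutathione peroxidase, from 399 ± 42.3 to 691 ± 73.97 CPM. Of 26 stress and immediate early genes 11 rose and 3 fell (11 and 6 adjusted over the list alone), the rises becoming 7 without KO 3 and the falls 5 without WT 3 and 0 without WT 1, WT 2, KO 2 or KO 3 (5, 6, 5 and 3 at an unadjusted p under 0.05 in edgeR); DESeq2 called 6 falls. Hspa1a and Hspa1b, near-identical heat shock genes whose counts may be shared, rose from 4.56 ± 0.613 to 9.96 ± 1.43 CPM and from 6.29 ± 1.78 to 13.7 ± 2.802 CPM, the second losing its call without KO 3. Camera called neither of these last lists (adjusted p of 0.173 and 0.235).

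**Figure D3:**
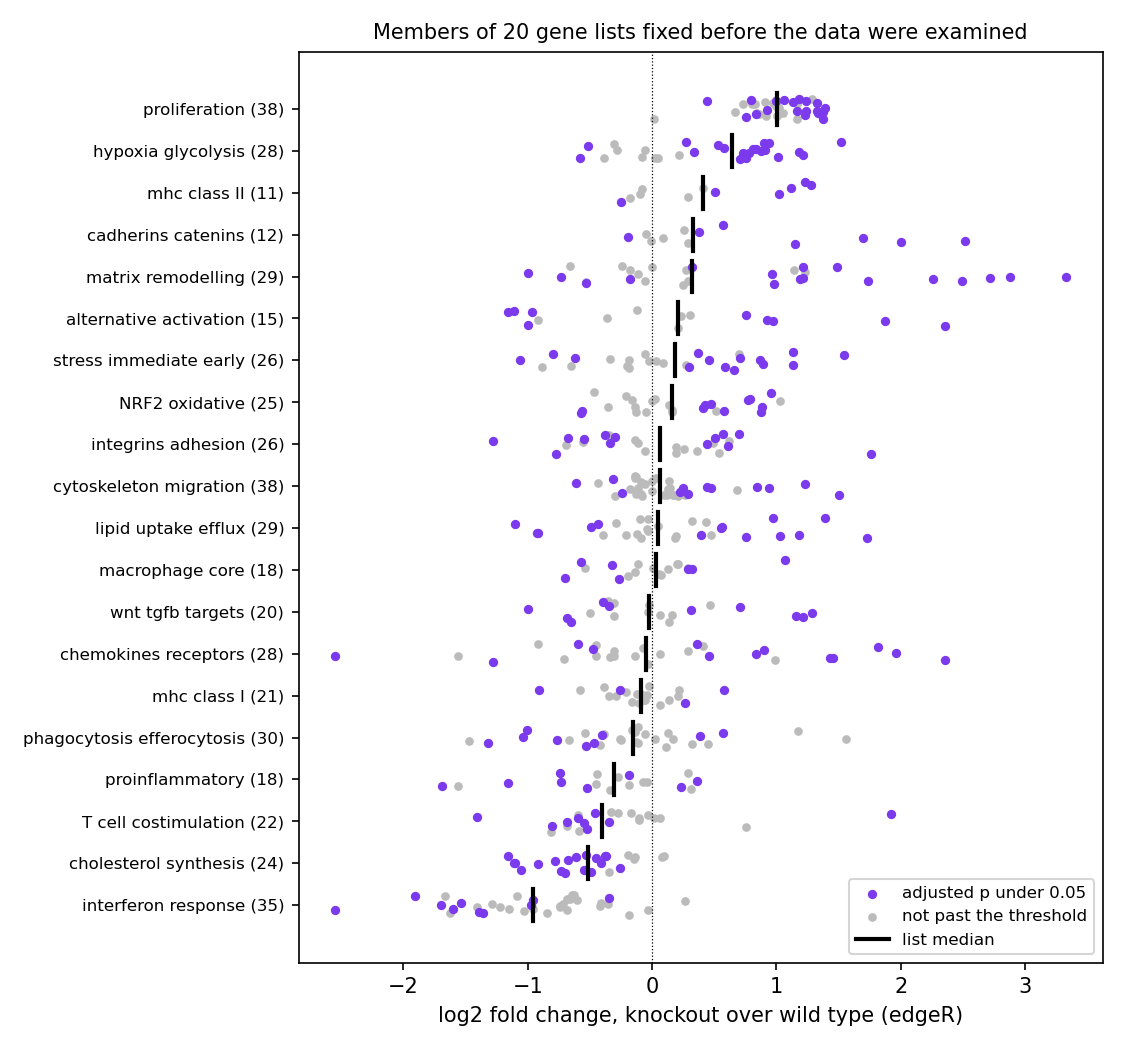
Log2 fold change of KO over WT for the members of the 20 pathway lists, in purple where edgeR's adjusted p was under 0.05 and in grey otherwise, with the list median as a black bar and the number of tested genes in brackets. Medians run from -0.96 for the interferon response to 1.00 for proliferation.

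Across all 31 lists camera called 5 with the preset correlation, the same 5 being called without any 1 library. The correlation between genes estimated for these lists was far above the preset 0.01. It was 0.95 for proliferation, 0.89 for the interferon response, 0.32 for cholesterol synthesis, 0.27 for hypoxia and glycolysis and 0.19 for costimulation. The preset therefore gives p-values that are too small for them, and leaving out 1 library keeps the same preset. With an estimated correlation 0 lists were called and 0 had an unadjusted p under 0.05, the smallest being 0.0823; fry called 1 list, had 12 with an unadjusted p under 0.05, and its test for change in either direction called 26.

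Among markers of other cell types that a marrow culture could hold, single genes changed but camera called none of the 11 lists. Osteoclast markers came nearest, 6 of 12 rising and 1 falling, as also adjusted over the list alone (camera adjusted p = 0.0761). Ocstamp, a fusion protein of osteoclasts, rose from 1.04 ± 0.0611 to 3.57 ± 0.595 CPM. Of 6 erythroid and megakaryocyte markers 3 rose and 0 fell (4 adjusted over the list alone, and 1 without WT 1 over all genes; DESeq2 called 6 rises of 8 tested and limma-voom 3 of 6), Itga2b among them, together with Ppbp, a platelet chemokine, from 2.74 ± 0.608 to 5.53 ± 1.41 CPM, whose call was lost without WT 1 or KO 2. Among 17 neutrophil markers 0 rose and 1 fell in edgeR's test, with 1 rising and 1 falling at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone; DESeq2 called 2 falls and limma-voom 1, and edgeR called 1 rise without KO 1 or KO 2. The median log2 fold change of the neutrophil list was 0.525, its mean 0.41 and camera's direction up (adjusted p = 0.5245). The 1 fall in edgeR's test was Mmp8, 36.1 ± 8.33 against 24.95 ± 2.59 CPM, a call lost without any 1 of the 6 libraries. Monocyte markers had 1 rise and 1 fall of 12, as also adjusted over the list alone, and 2 falls of 13 in DESeq2. Fn1 rose, as given above, and F13a1, coagulation factor XIII A, fell from 1474 ± 235 to 535 ± 237 CPM, a call lost without WT 1, WT 2 or KO 3. Dendritic cell markers had 2 rises and 2 falls of 12, as also adjusted over the list alone, with a median of -0.22, a mean of 0.18 and a camera direction of down. Without WT 1, WT 2 or KO 3 they had 1 rise and 1 fall, and without KO 2 also 1 fall. Irf4, a transcription factor, fell from 9.49 ± 1.56 to 5.02 ± 0.7899 CPM. Of 5 B cell markers 1 rose and 1 fell (2 and 1 adjusted over the list alone). DESeq2 called 2 rises of 7, and limma-voom 0 rises of 5 with 2 at an unadjusted p under 0.05. Ighm fell from 117 ± 13.1 to 54.4 ± 14.01 CPM, and Igkc, a light chain constant region whose reads can be split among loci, was at 9.99 CPM in KO 2 against 1.51 and 0.897 in the other KO libraries. Igkc lost its call without WT 1, WT 2 or WT 3, and the B cell list had 0 rises without WT 1 (2 at an unadjusted p under 0.05 in edgeR) and 3 rises and 2 falls without KO 1.

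The remaining marker lists were short. Of 7 endothelial markers 1 rose and 1 fell, as also adjusted over the list alone, with a median of 0.26, a mean of -0.03 and a camera direction of up. Eng, endoglin, rose from 27.5 ± 3.59 to 42.01 ± 7.81 CPM, and Egfl7 fell from 3.17 ± 0.613 to 1.41 ± 0.485 CPM, calls lost without WT 1, WT 2 or KO 3 and, for Eng, KO 2. Of 4 stromal markers 1 rose, as also adjusted over the list alone, with a median of -0.23, a mean of 0.28 and a camera direction of up. Nes, the intermediate filament protein nestin, rose from 19.1 ± 5.77 to 78.3 ± 27.4 CPM. Of 3 mast cell and basophil markers 1 rose (2 adjusted over the list alone, 2 of 4 in DESeq2 and 2 in limma-voom). Kit, the stem cell factor receptor, rose from 0.245 ± 0.02099 to 0.875 ± 0.408 CPM, a call lost without WT 1, WT 2 or KO 3. Of 2 measured T and NK cell markers 1 rose, as also adjusted over the list alone. Il7r, the interleukin-7 receptor, rose from 65.4 ± 10.00 to 148 ± 36.8 CPM. Of 2 adipocyte markers 1 rose, Fabp4; adjusted over the list alone 1 rose and 1 fell, as also without WT 3 or KO 1 or with DESeq2 over all genes. Without KO 1 the mast cell list had 2 rises and the T and NK cell list 1 rise and 1 fall.

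Some calls of single genes given above depended on other settings too. Without a filter, where more genes enter the adjustment, the calls of H2-Aa, H2-Ab1, Cd74, Fcgr2b, Mgll, Fgfr1, Ctsk, Cd200, Mamdc2, Dio2, Cxcl10, Ifit2, Rsad2, Ripor2, Irf1, Itgax, Pcdh7, Nlrc5, Icosl, Tyms, Mmp8, F13a1, Igkc and Eng were lost. Those of Mamdc2, Dio2 and Igkc were also lost with limma-voom. The call of Mmp8 was also lost with the deposited per-gene factors. Without WT 2 and KO 2 together, the calls of Lgals3, Fat3, Tnfsf9, Il7r, Tnfsf4, Kit, Ppbp, Egfl7, Dio2, Ripor2, Ifit2, Rsad2, Itgax, Pcdh7, Cd74, Tyms, Mmp8, F13a1 and Eng were lost.

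Because the mice were of a mixed 129S1/Sv x C57BL/6 background, the share of called genes was compared along chromosome 8. Of 689 tested genes there 256 (37.2%) were called against 35.1% elsewhere, an odds ratio of 1.09 (two-sided Fisher's exact test, p = 0.287). Within 10 Mb of Cdh11 58 of 150 genes were called (odds ratio 1.16, p = 0.390), and within 20 Mb 119 of 295 (odds ratio 1.25, 95% interval 0.979 to 1.59, p = 0.0646, adjusted p = 0.194 over the 3 regions in Fisher's exact test with Benjamini-Hochberg adjustment). Called neighbours within 10 Mb included Mt2, a metallothionein, which rose from 5.26 ± 0.927 to 16.5 ± 2.96 CPM, and Aars, the alanyl-tRNA synthetase, which rose from 112 ± 2.68 to 188 ± 22.9 CPM. Ciapin1, an iron-sulphur cluster assembly factor, rose from 21.99 ± 3.61 to 44.9 ± 3.91 CPM, Prmt7, an arginine methyltransferase, from 22.4 ± 0.301 to 33.3 ± 1.95 CPM, and Cmtm3 from 120.2 ± 8.74 to 168 ± 4.51 CPM. Ccl22 and Nlrc5, given above among chemokines and class I genes, also lie within 10 Mb of Cdh11. For genes in this interval the design does not separate flanking strain sequence from the loss of Cdh11.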

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

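The alternatives that use the deposited per-gene factors and that leave out 2 libraries together, and the interferon calls without single libraries, were added after the data were seen. The count of 4532 called genes stayed within 1.5 times under DESeq2 (4580), limma-voom (4637, or 6485 with sample quality weights), RLE factors (4522), library totals (4362, 2452 higher and 1910 lower), no filter (4036), a stricter filter (4467), the deposited per-gene factors (3702), limma on the deposited signal (3743), removal of chromosome 8 (4269) and adjusted p under 0.1 (6077). It was 1392 at adjusted p under 0.01 and 657 with a change of at least 2-fold, both stricter by construction, and 1370 without WT 2 and KO 2 together, with fewer libraries. Leaving out 1 library gave 1979 (WT 1) to 5456 (KO 1), with 2484 without WT 2, 2721 without KO 2 and 2384 without KO 3; of the 1979, 1963 were also called with all libraries. The 5 lists called by camera became 0 with an estimated correlation, 1 with fry and 8 with sample quality weights, and 5 to 8 when 1 library was left out; 8 were called without WT 2 and without KO 1. Why the quality weights added lists was not tested. The first component took 67.44% of the variance with 2000 genes, where more genes enter by construction. Of 119 named called genes, 74 (without WT 1) to 110 (without KO 1) were still called without 1 library, 78 without WT 2 and KO 2 together, 84 without a filter and at least 112 under the other tools, scalings and filters run on the counts; 0 reversed in these settings. Limma on the deposited signal was run for the count of genes and not for named genes. The stricter filter gave no value for Cdh11, whose log2 fold change ran from -0.84 to 0.05 over its alternatives without passing the threshold. At 3 libraries per genotype the simulated test recovered 56.7% of genes changed 1.5-fold, so small changes can be undetected.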

Other observations

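The tests of a culture state and of 1 WT library, and the 5 gene lists of the next paragraph, were chosen only after the results were seen; the interval around the megakaryocyte median was likewise added after the median was known.

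Beyond the lists fixed in advance, most genes of 2 lists that serve protein synthesis rose in KO. Of 42 ribosome biogenesis genes 41 rose and 0 fell, with a median log2 fold change of 0.58, and of 35 genes for amino acid synthesis, transport and tRNA charging 28 rose and 1 fell, with a median of 0.63. Camera's Benjamini-Hochberg adjusted p over these 5 lists was 5.03e-17 and 3.01e-13 with the preset correlation, and adjusted p = 0.306 for both with an estimated correlation. Guanylate-binding proteins and immunity-related GTPases, effectors induced by interferon, had 9 falls and 0 rises among 13, becoming 3 without WT 1, KO 2 or KO 3. Leukotriene genes had 2 rises and 4 falls of 11, and targets of the sterol receptor LXR 4 rises and 3 falls of 18, although its gene Nr1h3 rose; the first had 1 rise without any 1 library except KO 1 and 2 falls without WT 1 or WT 2, and the second 2 rises without WT 1 and 5 falls without KO 1. DESeq2 called 1 rise in the first and 5 falls of 19 in the second. Camera called the list of guanylate-binding proteins and immunity-related GTPases with the preset correlation (adjusted p = 3.7e-05), but not with an estimated correlation (adjusted p = 0.4026). It did not call the leukotriene and LXR lists with the preset correlation (adjusted p of 0.3522 and 0.5006). Because the lists were chosen from these libraries, their counts are not independent evidence of direction.

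A pair of genes differed widely between libraries of the same genotype, as noticed after their values were seen. Both were highest in KO 2 and KO 3, whereas WT 1 was low for Clba1 and high for Gm6166. Clba1 stood at 4.10, 4.04 and 29.9 CPM in WT 1, WT 2 and WT 3 and at 3.51, 31.3 and 61.5 CPM in KO 1, KO 2 and KO 3. The processed pseudogene Gm6166 stood at 24.4, 2.83 and 23.03 CPM in WT and 2.14, 42.6 and 49.8 CPM in KO.

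The breadth of the difference, 4532 called genes, was weighed first. Among the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes, the real one, and the highest of the others called 2. These 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes within each group, so a difference between genotypes widens the spread there and lowers the calls. GC or length bias is argued against as a main cause, since GC content with transcript length accounted for 1.78% of the variance of fold change. Carried-along strain sequence around the targeted locus was not decided. Within 20 Mb of Cdh11 lay 2.63% of called genes, but only 295 tested genes lie there, so the bound for that cause was out of reach. Direct effects inside that interval could cover at most its 119 called genes. Effects of such sequence on genes elsewhere, and strain differences at other loci, were not tested. A culture state that also differs between dishes of one genotype may contribute: across genes, which are not independent replicates, the main axis of differences within genotypes correlated with the fold change between genotypes at r = 0.601 (0.349 from WT alone, 0.573 from KO alone). On that axis KO 1 scored -25.37 and KO 2 21.96, and the design does not separate such a state from an effect of the genotype that varies between animals.

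The lower values of interferon-stimulated genes could reflect 1 WT library with a higher interferon level. Without WT 2 the list's median moved from -0.96 to -0.43, between the bounds of -0.2 and -0.5 set for a decision. Part of the difference thus rests on WT 2, and with 2 WT libraries left, the remainder and a lower level in KO cannot be told apart from further differences between single dishes.

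Some platelet and megakaryocyte transcripts, noticed after their values were seen, were higher in KO, such as Gp1ba with 6 counts over the WT and 63 over the KO libraries, which could come from megakaryocytes or platelets in the dishes; the list fixed in advance was not called (camera with Benjamini-Hochberg adjustment, adjusted p = 0.150). The median log2 fold change of 15 tested markers added for this question was 0.48. It was also 0.48 for the 13 that are in no other list (95% interval -0.15 to 1.45), Vwf and Ltbp1 having been seen as members of other lists. The first value lies under the bound of 0.5 set in advance for arguing against that source. The margin is less than its spread (95% interval of the median -0.06 to 1.29). The explanation was therefore left undecided, where the bound alone would have rejected it on the tested markers. Several of these markers, such as Plek and Fermt3, are also abundant in macrophages, and 7 of the 15 rose and 1 fell. The rest of the 21 added markers failed the filter and do not enter the median. Of these, Gp1bb went from 7 counts in WT to 32 in KO, Gp9 from 4 to 32 and Gp6 from 5 to 26. Trpc6 went from 7 to 25 counts and Gata1 from 4 to 14. Tubb1, also among them, had in contrast 18 counts in WT and 13 in KO. Pf4, a platelet chemokine, stood at 208 CPM in WT and 217 in KO. It had 19568 and 18994 counts, against 6 and 63 for Gp1ba. A small amount of platelet RNA need not show at that level, so Pf4 does not decide the question.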
